A study of Arabidopsis thaliana with 9 samples.

How the data were processed

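Siliques of Arabidopsis thaliana (accession Columbia-0), the fruits that hold the developing seeds, were collected 1 to 5 days after pollination, per the labels. The 9 samples were 6 mRNA libraries and 3 small RNA (sRNA) libraries. The mRNA libraries came from plants homozygous for the ago3-3 allele of ARGONAUTE 3 (AGO3), plants heterozygous for it and wild-type plants, 2 biological samples of each per the series design text. The sRNA libraries were total sRNA, sRNA recovered with AGO3 tagged with a FLAG epitope, and sRNA from a control immunoprecipitation with FLAG antibody in wild-type siliques, 1 library each without replication.

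The deposited mRNA table held estimated counts per gene, not scaled to depth, in 1 column per library. Of its 205572 values, 7.88% were not whole numbers, as when the authors' counting divides a read among several genes. The submitters' processing notes name HISAT2, featureCounts and the genome build TAIR10; versions and settings are not given in the sources used here, nor is the strand setting. Reads from overlapping genes, antisense pairs and near-identical copies could therefore not be told apart. The sRNA table held deposited read counts, as whole numbers, for consecutive 500 bp windows of the genome. The submitters' processing notes name Bowtie and TAIR10 for the series; read lengths, allowed mismatches and the handling of reads that fit several places are not given in the sources used here.

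Estimated counts were rounded to whole numbers before testing. Totals per mRNA library ran from 30338400 to 36259000, at which 3 counts correspond to 0.0827 to 0.0989 counts-per-million (CPM). Of 34262 rows, 22702 passed edgeR's expression filter and were tested. All chloroplast and mitochondrial rows held 0 counts, so leaving them out changed nothing. A list of transposable element genes planned before the data were examined was not formed, because the gene table used has no such class. Structural RNA rows, listed under other identifiers, numbered 1429.

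The quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM scaling was fitted to all 6 mRNA libraries together, with 3 residual degrees of freedom, a biological coefficient of variation of 0.185 and Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) are the log2 fold change divided by the root of the F statistic. DESeq2 1.42.0 (Wald test, independent filtering set for 0.05) was the alternative tool. The 17 gene lists, 202 genes in all and 2 to 20 per list, were fixed before the data were examined, as were the models, most of the other settings and the rule for named genes. The lists cover the ARGONAUTE family, RNA-directed DNA methylation, DNA methylation maintenance and demethylation, miRNA and post-transcriptional silencing, imprinted and endosperm genes, embryo and seed maturation, seed coat and flavonoids, vasculature and nutrient unloading, silique wall patterning and dehiscence, photosynthesis, pollen, petal and stamen identity, defence and jasmonate, abiotic and heat stress, cell cycle, circadian clock and trans-acting siRNA loci. They were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry. The rule named AGO3, its neighbour and close paralogue AGO2, up to 10 rising and 10 falling genes past the test with a mean log2 CPM of at least 1, and up to 4 members of each list past the test. Because no gene passed, every other mRNA gene named was chosen after its values were seen.

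An sRNA window counted as enriched when it held at least 20 reads in the AGO3 immunoprecipitate and its reads-per-million (RPM) plus 1 were at least 4 times those of the control, which takes at least 112 AGO3 reads, so the minimum of 20 had no effect. Named windows were the 10 largest ratios, the 5 most read windows of each library and the windows of trans-acting siRNA loci. Ratios carry exact binomial 95% intervals, which cover counting error only, since reads are not independent molecules. With 1 library per condition no p-value was computed across windows or genes; lists were instead set beside 10000 random lists of genes of similar length, as a description. Gene positions and names came from a table of assembly TAIR10.1, used to place nuclear genes at windows; the coordinates printed are those of the sRNA table (TAIR10, counted from 1). As a check, 326 miRNA genes had a median of 167 total sRNA reads at their own positions and 2 to 4 when moved by 500 to 5000 bp. Of the mRNA rows, 32548 matched a locus tag. The pericentromere was taken as 2.5 Mb either side of 15, 4, 14, 4 and 12 Mb on chromosomes 1 to 5. The sRNA totals were 37189850 reads for the AGO3 immunoprecipitate, 25613847 for the control and 40262802 for total sRNA. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

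The scripts were tested on simulated data. With 67 genes changed 2-fold, 55.2% were recovered for homozygous against wild type and 61.2% for each of the other comparisons; of 67 genes changed 4-fold, 95.5% to 97.0% were recovered. Among the unchanged genes, 15, 17 and 27 were called in the 3 comparisons. The recovered shares hold for the simulated data and cannot be carried over to the real libraries. There, for homozygous against wild type, AGO3 (log2 difference -3.15) and AT4G06945 (-2.04) were not called by edgeR (adjusted p = 0.142 for each). A lack of calls therefore does not show that no gene changed 4-fold. All 200 windows raised 8-fold were recovered. The alternatives covered scaling, filtering, the tool, the threshold, gene length (known for 99.1% of tested genes; GC content was not used here), the replicate number as a block, each library left out in turn, and the window rule. Replicates within a genotype differed by more than sampling noise, with a mean chi-square per gene of 22.7 to 105.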

Results

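The series measured mRNA in siliques of ago3-3 homozygous, ago3-3 heterozygous and wild-type plants, with 2 libraries per genotype, and sRNA in 1 total library, 1 AGO3 immunoprecipitate and 1 control immunoprecipitate. AGO3 is an ARGONAUTE, a protein that binds sRNAs and is guided by them to matching transcripts or loci. The mRNA libraries held 30338400 (wild type replicate 2) to 36259000 (wild type replicate 1) counts. AGO3 and AGO2 were to be named whatever their values, and every other mRNA gene named here was chosen after its values were seen. The first principal component carried 37.3% of the variance and did not follow genotype: homozygous replicate 2 lay at 44.2 and wild type replicate 1 at 49.9, and the other 4 libraries lay between -27.1 and -20.0. Structural RNA made up 3.04% to 8.13% of counts, with the lowest share in wild type replicate 1 and the highest in wild type replicate 2.

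AGO3 mRNA followed the genotype labels. It stood at 2.70 CPM ± 0.831 (SD, n = 2) in homozygous, 12.3 CPM ± 0.403 (SD, n = 2) in heterozygous and 24.0 CPM ± 9.0 (SD, n = 2) in wild-type siliques. The log2 difference was -3.15 ± 0.31 (SE) between homozygous and wild-type siliques, 8.90-fold lower, -0.96 ± 0.28 (SE) between heterozygous and wild-type siliques, and -2.19 ± 0.31 (SE) between homozygous and heterozygous siliques. In edgeR's quasi-likelihood test over all genes the adjusted p was 0.142, 0.955 and 1.0 respectively, so AGO3 did not pass. Adjusted over the list alone, AGO3 passed among the 9 tested ARGONAUTE genes for homozygous against wild type (adjusted p = 0.000112, edgeR) and homozygous against heterozygous (adjusted p = 0.00122, edgeR), and not for heterozygous against wild type (adjusted p = 0.0891, edgeR). DESeq2 called AGO3 for homozygous against wild type (adjusted p = 1.7e-19) and homozygous against heterozygous (adjusted p = 7.5e-08), and gave no adjusted p for heterozygous against wild type. AGO2, which lies beside AGO3 and resembles it, so that reads could be shared, differed by 0.20 ± 0.13, 0.16 ± 0.13 and 0.04 ± 0.13 (log2, SE) in the same 3 comparisons and passed none.

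**Figure D1:**
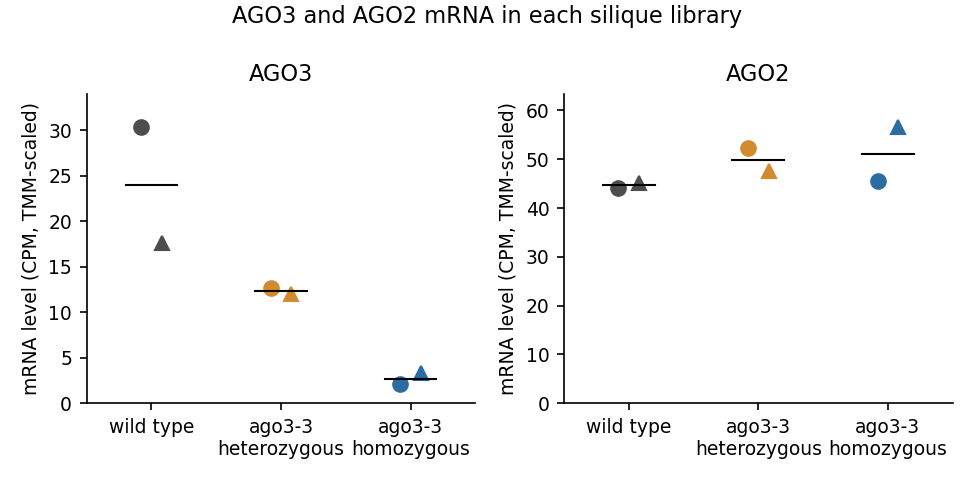
mRNA level in counts-per-million (CPM; vertical axes, TMM-scaled) of AGO3 and AGO2 in the 6 libraries, as circles for replicate 1 and triangles for replicate 2, with the group mean as a line. AGO3 lies at 2.11 and 3.29 CPM in homozygous, 12.6 and 12 in heterozygous and 30.4 and 17.7 in wild-type siliques, and AGO2 lies between 44.1 and 56.7 CPM in all 6 libraries.

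The comparison of homozygous with wild-type siliques asks which transcripts differ when AGO3 is mutated. Pollen genes were lower in homozygous siliques: 7 of 7 tested members were below wild type, with a median log2 difference of -0.93. The arabinogalactan protein genes of pollen AGP11 (-1.86 ± 0.28, SE) and AGP6 (-1.23 ± 0.29, SE), the receptor-like kinase gene ANX1 (-1.24 ± 0.33, SE) and the pectin methylesterase gene VGDH1 (-0.78 ± 0.24, SE) were the 4 members past the test when adjusted over the list alone. Defence and jasmonate genes were higher in 10 of 11 tested members, with a median of 0.62; the vegetative storage protein genes VSP1 (1.19 ± 0.29, SE) and VSP2 (1.86 ± 0.43, SE), both induced by jasmonate, passed over the list alone. The pathogenesis-related gene PR2 stood at 15.6 CPM in homozygous replicate 2 and at 1.16 CPM or less in the other 5 libraries. FLS1, a flavonol synthase, was lower by a log2 difference of -0.48 ± 0.10 (SE) and passed over its list alone. The other 15 lists gave no call, and imprinted and endosperm genes were higher in 7 and lower in 6 of 13 members.

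Both list calls came from camera with a preset correlation (adjusted p = 1.2e-12 for pollen, 1.1e-06 for defence and jasmonate). Neither held with an estimated correlation (adjusted p = 0.578 for each), and the defence call was lost without homozygous replicate 2 (adjusted p = 0.113). Over all 22702 tested genes, edgeR called 0, with a smallest adjusted p of 0.142; 1293 genes had an unadjusted p under 0.05 (483 higher, 810 lower), where chance alone gives 1135. DESeq2 called 76 genes, 10 higher and 66 lower. Of the 76, 4 were members of the fixed lists, all lower. They were AGO3, FLS1 and the pollen genes AGP11 and AGP6 (log2 difference of AGP6 -1.23, adjusted p = 0.013, DESeq2). Genes expressed together, such as those of pollen, can fall together, so the 76 cannot be read as independent changes. Genes picked from these 76 after their values were seen were, lower in homozygous siliques, CSD2, a copper/zinc superoxide dismutase (log2 difference -0.95, adjusted p = 2.4e-10), FER1, a ferritin (-0.74, adjusted p = 1.4e-05), and AGP11 (-1.86, adjusted p = 4.5e-07). Higher were HIS4, a histone H4 gene (1.15, adjusted p = 0.00016), and EXPA1, an expansin (0.61, adjusted p = 0.0056). Without homozygous replicate 2 and wild type replicate 1, an exclusion chosen after the data were seen, edgeR called 54 genes, of which 6 were among the 76.

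Heterozygous siliques were compared with wild type to see the effect of 1 mutant copy. Seed coat and flavonoid genes were lower in 16 of 18 members, with a median of -0.30; FLS1 (-0.49 ± 0.10, SE) passed over the list alone, and chalcone synthase CHS (-0.41 ± 0.13, SE) and dihydroflavonol reductase DFR (-0.44 ± 0.13, SE) did not. RNA-directed DNA methylation genes were higher in 16 of 20 members, with a median of 0.09; IDN2, a double-stranded RNA-binding protein of this pathway, passed over the list alone (0.55 ± 0.11, SE). Embryo and seed maturation genes were higher in 7 of 10 members, with a median of 0.40; the largest difference was that of the seed storage protein gene CRU1 (4.81 ± 1.72, SE), at 6.25 and 30.5 CPM in heterozygous and 0.0541 and 1.36 CPM in wild-type libraries.

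These 3 list calls (camera with a preset correlation, adjusted p = 4.4e-06, 0.0134 and 0.00911) were not kept with an estimated correlation (adjusted p = 0.675, 0.675 and 0.741). The methylation call was lost without heterozygous replicate 2 (adjusted p = 0.272), wild type replicate 1 (0.295) or wild type replicate 2 (0.0527), and the embryo call without heterozygous replicate 2 (0.112) or wild type replicate 1 (0.540). The seed coat call was also lost without homozygous replicate 2 and wild type replicate 1 together (adjusted p = 0.0592, camera). edgeR called 0 of 22702 genes; 1006 had an unadjusted p under 0.05 (409 higher, 597 lower), fewer than the 1135 of chance, and DESeq2 called 18, 2 higher and 16 lower. Picked from the 18 after their values were seen were ELIP1, an early light-induced protein gene (-1.32, adjusted p = 0.00011), KIN2, a cold-induced gene (-0.96, adjusted p = 0.0075), FLS1 (-0.49, adjusted p = 0.015) and, higher, IDN2 (0.56, adjusted p = 0.037).

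Homozygous siliques were then set against heterozygous ones. All 7 tested pollen genes were lower in homozygous siliques, with a median of -0.85, and 6 passed over the list alone, among them AGP11 (-1.42 ± 0.28, SE) and PPME1 (-1.40 ± 0.41, SE). The member that did not pass was VEX1 (-0.76 ± 0.56, SE). Defence and jasmonate genes were higher in 11 of 11 members, with a median of 0.93, and none passed over the list alone. Seed coat and flavonoid genes were higher in 15 of 18 members, with a median of 0.20 and none past the test. The pollen (adjusted p = 5.9e-17), defence (8.8e-10) and seed coat (0.00124) calls of camera were lost with an estimated correlation (adjusted p = 0.427, 0.634 and 0.634), and the last 2 also without homozygous replicate 2 (0.0855 and 0.148). edgeR called 0 genes, 745 had an unadjusted p under 0.05 (322 higher, 423 lower, chance 1135), and DESeq2 called 23, 5 higher and 18 lower. Those higher included PCC1, a gene linked to pathogen response and the circadian clock (2.44, adjusted p = 0.045), and ELIP1 (1.15, adjusted p = 0.0039). Both were low in heterozygous libraries and not raised above wild type in homozygous ones. PCC1 stood at 25.7 and 23.9 CPM in homozygous, 4.05 and 5.05 in heterozygous and 28.2 and 10.1 in wild-type libraries. ELIP1 stood at 77.8 and 56.6, 36.7 and 23.6, and 84.0 and 67.3 CPM in the same order. Of the 23, 15 were also among the 76 that DESeq2 called for homozygous against wild type. AGO3 and the pollen gene AGP11 (-1.43 against heterozygous, adjusted p = 0.0031, DESeq2), both lower, were among the 15. Both comparisons use the same homozygous libraries, so part of this overlap may come from them.

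**Figure D2:**
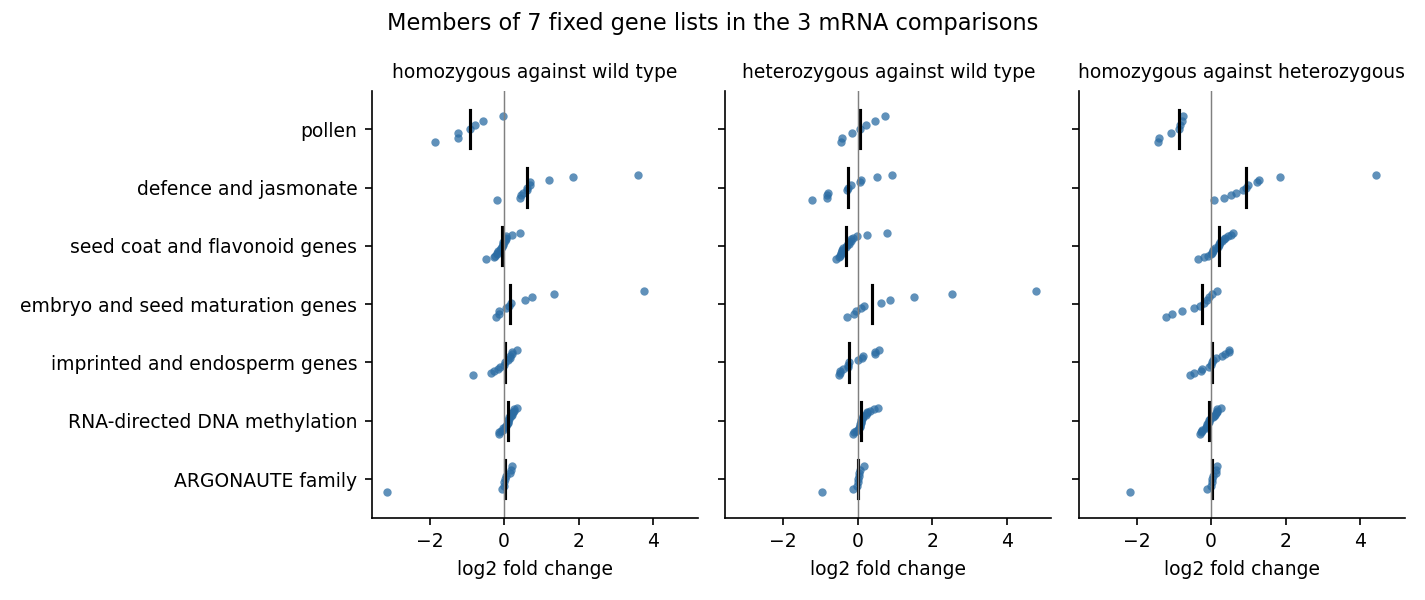
Log2 fold change (horizontal axes) of each tested member (points) of 7 gene lists fixed before the data were examined, in the 3 mRNA comparisons, with the median of each list as a black line. The pollen medians are -0.93, 0.07 and -0.85 from left to right, and AGO3 is the lowest point of the ARGONAUTE family at -3.15, -0.96 and -2.19.

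**Figure D3:**
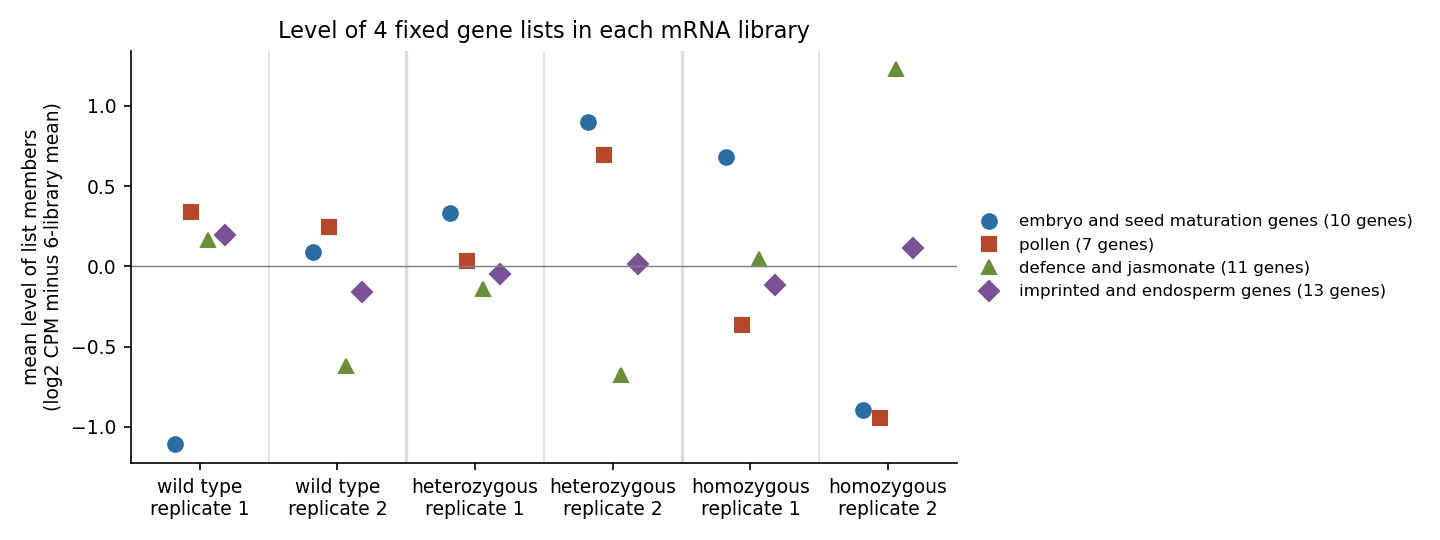
Mean level of the members of 4 gene lists in each of the 6 mRNA libraries (log2 CPM minus the mean of all libraries). Embryo and seed maturation genes are lowest in wild type replicate 1 (-1.11) and homozygous replicate 2 (-0.89), and pollen genes lie at -0.36 and -0.94 in the 2 homozygous libraries and between 0.03 and 0.69 in the other 4.

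The fold changes of homozygous and heterozygous siliques against wild type correlated across the 22702 genes, which are not independent replicates, with r = 0.579. Both comparisons use the same 2 wild-type libraries. In 20 simulations of all 6 libraries without any genotype difference, wild type included, r was 0.50 ± 0.016 (SD). Genes were drawn independently there, so the simulated values leave out variation that genes share within a real library. The covariance was 0.116 against 0.0804 simulated. At an unadjusted p under 0.05, 227 genes were lower in both, against 101 simulated and 21.3 for independent lists; 133 were higher in both, against 143 simulated and 8.70 for independent lists. With 2 wild-type libraries the controls could not be divided between the comparisons without leaving 1 library to each, so part of the excess may come from the shared controls. The excess depended on the libraries used: without homozygous replicate 1 the correlation was 0.234, below its own simulated 0.379 ± 0.0141 (SD), and without heterozygous replicate 1 it was 0.399, within the simulated range of 0.358 to 0.406. Without wild type replicate 1 it was 0.793 against 0.736 ± 0.0130 (SD).

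The sRNA libraries were compared to find the loci whose sRNAs were recovered with AGO3. Reads from miRNA genes made up 21.5% of the AGO3 immunoprecipitate, 22.7% of the control and 26.5% of total sRNA, and the most read window in all 3 held MIR166a (chromosome 2, 19176001 to 19176500), at 29194, 32570 and 33507 RPM. MIR159a was 3.47 times as abundant in the AGO3 immunoprecipitate as in the control (95% interval 3.4 to 3.5) and 0.790 times as abundant as in total sRNA. It was named after its values were seen, as the highest of 15 miRNA families examined; the most read genes of the other 14 lay between 0.479 (MIR390a) and 1.46 (MIR403) times the control, 6 of them under 1. The windows of MIR166b, MIR166c, MIR166d, MIR166f and MIR166g held 832478 to 848182 AGO3 and 612225 to 620003 control reads each, as when the same reads are counted at several copies, so the shares may count a read more than once. With only the most read gene of each miRNA family, an alternative chosen after the data were seen, they were 7.83%, 8.06% and 11.2%. Without the 100 most read windows the miRNA shares were 1.46%, 1.55% and 2.81%, and by windows of at least 20 reads counted once 0.550%, 0.485% and 0.584%, the last form with AGO3 above the control. The pericentromere held 22.9%, 25.4% and 24.7% of reads, but 47.4%, 43.3% and 53.7% of windows of at least 20 reads, again with AGO3 above the control, 37.5%, 37.5% and 39.8% with windows capped at 1000 reads, and 12.1%, 14.7% and 14% with 1.5 Mb either side. The cutoffs of 20 and 1000 reads were not scaled to depth, and the control library held the fewest reads. Both shares by windows rank in the order of depth (control, AGO3, total sRNA), so AGO3 above the control may come from depth. None of these shares has a replicate check, and intervals cover counting error only.

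By the fixed rule 1314 windows were enriched over the control. They held 15.5% of AGO3 immunoprecipitate reads, 1.62% of control reads and 2.97% of total sRNA reads, and 972 of them also met the ratio of 4 over total sRNA. An enriched neighbour stood beside 69.3% of them. In the reverse direction 619 windows were enriched in the control, and 13.1% had such a neighbour. Windows under 112 AGO3 reads cannot meet the ratio; of the others, 10.5% were enriched on chromosome arms and 3.74% in the pericentromere, 12.8% in protein-coding genes and 1.53% in pseudogenes. Part of these contrasts followed read depth: among windows of at least 1000 AGO3 reads the shares were 26% and 18%, and 31% and 12%, in the same order. The largest ratio of RPM plus 1 was 93.0, in a window on chromosome 2 (11812501 to 11813000) at the non-coding RNA gene AT2G00840, with 3691 AGO3, 2 control and 89 total reads. Next came 74.6, on chromosome 5 (17498001 to 17498500) in the protein-coding gene AT5G43550, and 48.4, on chromosome 1 (18974001 to 18974500) with no gene within 1 kb.

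**Figure D4:**
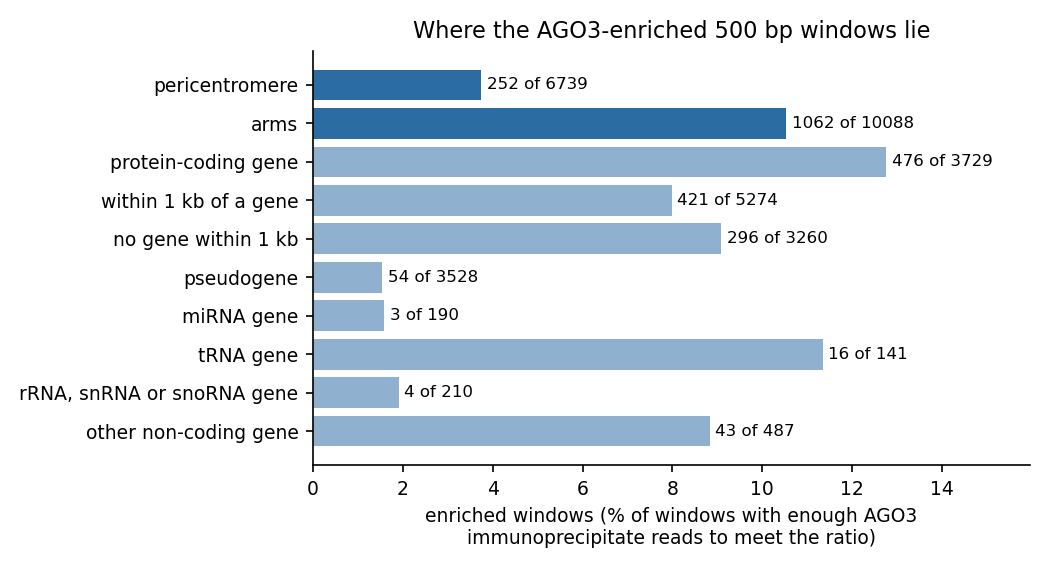
Share of windows (horizontal axis, %) that were enriched in the AGO3 immunoprecipitate over the control, among windows with at least 112 AGO3 reads, the fewest that can meet the ratio, by chromosome region (dark bars) and by annotation (light bars), with the window counts beside each bar. Arms reach 10.5% and the pericentromere 3.74%.

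Of the 14 imprinted and endosperm genes, 3 overlapped an enriched window, against 1.2% of other protein-coding genes, and 7 of 10000 random lists matched on length held as many; 16 lists were examined in this way, for overlap and within 1 kb. The 3 were AGL62, a MADS-box regulator of endosperm cellularisation (33.6 times the control over all 6 windows of the gene, 4 of them enriched, interval 30.4 to 37.2), the related AGL91 (15 over 2 windows, both enriched, 14.6 to 15.4) and the auxin biosynthesis gene YUC10 (4.07 over 5 windows, 4.01 to 4.14). Only 1 window of YUC10 was enriched, at 32.5 times the control (28.3 to 37.6). The other members with at least 112 AGO3 reads over the gene lay below the control. They were AGL36 at 0.930, AGL90 at 0.768, FWA at 0.775 and SDC at 0.618 times the control. The random lists were matched on length and not on sRNA reads. Only 3729 of 145997 windows classed as protein-coding held the 112 AGO3 reads that enrichment takes. The 7 of 10000 may therefore reflect which genes have sRNA at all, and does not show a preference of AGO3 for imprinted genes. The enriched AGL62 windows ran from 24306001 to 24308000 on chromosome 5, the AGL91 windows from 2091001 to 2092000 on chromosome 3, and the YUC10 window from 18093001 to 18093500 on chromosome 1. Of the methylation maintenance list, MET1 and DDM1 overlapped an enriched window, and that of DDM1 also held a tRNA gene. The AGO3 locus itself stood at 7.85 times the control over its 10 windows (7.19 to 8.59), of which 6, from 11189501 to 11192500 on chromosome 1, were enriched; reads from the AGO3:FLAG construct cannot be separated from those of the gene. FRK1 and LOX2 of the defence list lay within 1 kb of an enriched window, and no member of the other 12 lists did. Of the trans-acting siRNA loci, TAS4 had 1 enriched window (25.7 over its 3 windows, 13.8 to 54.0, on 373 and 10 reads), and TAS1A, TAS1B, TAS1C, TAS2 and TAS3A lay between 0.955 and 1.36 times the control.

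Genes at enriched windows were followed in the mRNA data. For the 260 tested genes that overlapped one, the median log2 difference was -0.02 for homozygous against wild type, -0.03 for heterozygous against wild type and 0.01 for homozygous against heterozygous siliques. camera of limma gave an adjusted p = 0.940, 0.660 and 0.800, and called none. Tested for change in either direction with fry of limma, the overlapping genes passed for homozygous against wild type (adjusted p = 0.0456), and not once AGO3, itself one of them, was left out (adjusted p = 0.154); this test was chosen after the data were seen. The median for homozygous against wild type lay at the 2.54 percentile of 10000 random lists of similar expression. The 534 genes with a window within 1 kb gave no call either (adjusted p = 0.940, 0.660 and 0.800, camera of limma). At the imprinted genes the mRNA levels of AGL62 (-0.01 ± 0.42, SE), YUC10 (0.15 ± 0.58, SE) and AGL91 (0.10 ± 0.42, SE) differed between homozygous and wild-type siliques by less than their error.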

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

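The alternatives called DESeq2 at its default filtering, protein-coding genes alone, crossed pairing, near-equal windows, 1 gene per miRNA family, fry in either direction and the exclusion of 2 libraries were chosen after seeing the data; the others were planned. The count of 0 changed genes from edgeR held under both other scalings, the mean count of 50, both other thresholds, 4 libraries alone, the length trend and protein-coding genes alone, in all 3 comparisons. DESeq2 called 76, 18 and 23 genes (homozygous against wild type, heterozygous against wild type, homozygous against heterozygous), and 72, 13 and 20 with its default alpha for independent filtering. The 76, 18 and 23 came from 16331, 7669 and 20661 genes given an adjusted p, so these counts have unlike bases. Among the 76, ENSRNA049495668 and U4.2 held the same values in every library. AT2G35750 and AT2G08770 held nearly the same, at 108 and 106 CPM in homozygous replicate 1 and 170 and 168 CPM in wild type replicate 1. With no filter edgeR called 4 in the first comparison: AGO3, AGP11, CSD2 and AT4G06945. Without homozygous replicate 2 and wild type replicate 1 it called 54, 22 and 5; 1 residual degree of freedom is left, lone samples are assumed to vary like the others, and 6 of the 54 are among the 76. Leaving out single libraries gave 0 to 3, 0 to 4 and 0 to 1 calls, the highest without wild type replicate 2 (in the last comparison, PCC1, also without wild type replicate 1). AGO3 kept its direction throughout, from -3.51 to -2.71, -1.29 to -0.52 and -2.54 to -1.91, with adjusted p from 1.7e-19 to 0.905, 0.360 to 1 and 7.5e-08 to 1; it passed in 4 of 17, 0 of 16 and 2 of 17 alternatives. The cause of these differences was not tested.

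With the replicate block edgeR called 0 genes in each comparison, also with the length trend removed, and the list calls numbered 2, 3 and 3 as without it; the correlation of the 2 genotypes was 0.589. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.088 (homozygous and heterozygous), -0.364 (homozygous and wild type) and -0.045 (heterozygous and wild type). A crossed pairing of homozygous and wild-type libraries gave 0 calls as first computed, with heterozygous libraries keeping their numbers, and 27 calls (4 higher, 23 lower) in a second form, with heterozygous libraries outside the pairs, which was adopted when its count was already known.

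The list calls (2, 3 and 3) all ended with an estimated correlation (0, 0 and 0) and with fry (0, 0 and 0). Without homozygous replicate 2 and wild type replicate 1 they numbered 3, 0 and 1, and without single libraries 2 to 4, 1 to 6 and 1 to 4. The correlation of fold changes was 0.606 over genes with a mean count of 50 and 0.234 to 0.793 without single libraries; the simulated values for the same subsets ran from 0.379 to 0.736, and the observed one lay below its own without homozygous replicate 1, within the simulated range without heterozygous replicate 1, and above the range without each of the other 4. For genes at enriched windows, the other settings of camera gave no p under 0.05. fry in either direction gave 0.0228 for overlapping genes in homozygous against wild type, before adjustment, and 0.141 without AGO3.

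Enriched windows numbered 3184 at a ratio of 2, 637 at 8, 630 with a pseudocount of 5 RPM, 1791 with 0.5 RPM, 1632 without the 100 most read windows in the totals, 1536 by median ratios, 1347 over total sRNA and 972 over both; minimums of 10 and 50 reads test nothing, since the ratio already takes 112 reads, and leaving out near-equal windows, sought only among those of at least 1000 total reads, where 27 of 2863 were found, removed none and tests little. The pericentromere share, in the order AGO3, control and total, was 28.4%, 32.2% and 32.3% without the 100 most read windows, 12.1%, 14.7% and 14% with 1.5 Mb either side, 37.5%, 37.5% and 39.8% with windows capped at 1000 reads, and 47.4%, 43.3% and 53.7% with windows of at least 20 reads counted once. The miRNA share fell to 7.83%, 8.06% and 11.2% with 1 gene per miRNA family, which also leaves out copies of different sequence, 1.46%, 1.55% and 2.81% without the 100 most read windows, 1.18%, 1.26% and 1.36% when capped, and 0.550%, 0.485% and 0.584% by windows; a few windows hold most miRNA reads. The cutoffs of 20 and 1000 reads were not scaled to the depth of each library, which limits the shares that use them. Depth limits genes under about 0.1 CPM, and the lack of sRNA replicates limits every sRNA ratio.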

Other observations

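The tests below were chosen after the result was seen, except that of the second pollen list, whose prediction was written before its values were seen although the list was drawn up once the pattern was known.

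Abiotic and heat stress genes were divided in heterozygous against wild-type siliques, 5 higher and 4 lower, and none passed when adjusted over the list alone. RD29B, among the higher, held 13 and 11 counts in heterozygous and 3 and 0 in wild-type libraries, the latter at or under the floor of 3, so no fold is given. HSP70-4 (1.00 ± 0.37) was higher, and RD29A (-0.74 ± 0.32), COR15A (-0.92 ± 0.37) and KIN1 (-0.99 ± 0.42, log2, SE) lower; these genes were picked after their values were seen. The circadian clock list was lower in 10 of 12 members in heterozygous siliques (camera adjusted p = 0.0860). Photosynthesis genes were split 6 to 6 in homozygous siliques, and AGO1, AGO4, AGO5, AGO6, AGO7, AGO9 and AGO10 lay within 0.21 log2 of wild type in both mutant genotypes.

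Embryo and seed maturation genes differed between replicates: homozygous replicate 2 lay 1.58 log2 below replicate 1, wild type replicate 1 lay 1.2 below replicate 2, and heterozygous replicate 1 lay 0.57 below replicate 2. Exchanged labels are argued against by AGO3, at 3.29 CPM in homozygous replicate 2, below both heterozygous libraries, and a difference in structural RNA because its shares shift other genes by only -0.0111 log2 in homozygous and 0.0777 in wild-type siliques. Less seed tissue alone, without a difference in seed stage, is argued against in wild type replicate 1. Less seed tissue together with an earlier stage was not tested. The median gap of this library to replicate 2 was 0.600 log2 for imprinted and endosperm members and -1.15 for embryo members, 1.75 apart (SD 0.673 and 1.24 over members). Less seed tissue stays open in homozygous replicate 2, whose median gaps to replicate 1 were 0.0809 and -0.913, 0.994 apart (SD 0.509 and 2.06). That bound, the larger SD, was set after 0.994 was known. The SD of the imprinted members alone, used first, would argue against less seed tissue alone in both genotypes. Either SD measures the spread between genes, not the error of the difference. An earlier seed stage may be involved and stays open: a second list of seed filling genes had gaps of -2.97 in homozygous and -0.818 in wild-type siliques, but -2.85 between the heterozygous replicates too, and several members lie near 0 counts.

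The mean level of the pollen list was lower in both homozygous libraries than in the other 4, and so were 5 of its 7 members, not VGD1 or VEX1. Other scalings gave list medians of -0.92 to -0.91 against wild type and -0.86 to -0.85 against heterozygous, and moved the median of all genes by at most 0.0119 log2. The median of all tested genes was 0.008 log2 against wild type and 0.006 against heterozygous. A scaling factor moves all genes of a library alike. That property, and not the medians under other scalings, argues against scaling as the reason why pollen genes lay below other genes. Those medians could hardly have come out otherwise and add no support. The split of the first principal component is argued against, since the list in wild type replicate 1 lay 0.700 log2 above the higher homozygous library. A candidate explanation is less pollen on or in the homozygous siliques: in a second list of pollen genes 11 of 11 members were lower than wild type and 10 of 11 lower than heterozygous, the median nearer to 0 being -0.73. The second list was read in the same libraries as the first. It cannot tell less pollen from a lower level of these transcripts for another reason, including the genotype. Such another reason was not tested, and the first list did not pass with an estimated correlation (camera adjusted p = 0.578 against wild type).

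Windows enriched in the AGO3 immunoprecipitate clustered: 69.3% had an enriched neighbour, against 13.1% of windows enriched the other way. This argues against counting noise in separate windows. It does not exclude chance between single libraries, which may act on whole loci of several windows. The sets also differ in size (1314 and 619 windows) and in median level in their own library (21.8 and 7.81 RPM). Without the 100 most read windows in the totals 1632 windows were enriched, so the count did not fall. Scaling by a few windows stays undecided, because this setting raises every RPM while the added 1 RPM stays. That alone raises the count. Reads counted at every copy of a repeat stay open: 0% of the 212 enriched windows with at least 1000 total reads had a window of nearly equal counts (within 1%), but only 27 of all 2863 windows of that depth had one, so this test excludes nothing. Binding by AGO3 is a candidate explanation, but a difference between 2 single preparations, one from tagged and one from wild-type plants, cannot be separated from it without replicates.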
